A study of Mus musculus with 6 samples.

How the data were processed

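Single-cell RNA libraries were made from sciatic nerves of C57BL/6 mice at P0, P7, P14, P28 and P60, pooling 22, 21, 18, 15 and 13 animals of both sexes, and 1 library from lumbar dorsal root ganglia of 8 animals at P14. Per the labels' protocols, tissue was dissociated with collagenase and papain in a warm water bath, red cells were lysed and dead cells removed with beads, and libraries followed a droplet protocol with unique molecular identifiers (UMIs). The ganglion sample is titled as cells while the study's design text speaks of nuclei, and its median mitochondrial share of 0.0653% against 2.31% to 3.06% in the nerve libraries led it to be treated as nuclei. The nerve titles number the libraries as replicates 1 to 5, but these numbers stand for the ages, and there was 1 library per age.

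The deposited files hold a UMI count per gene and barcode for each library, already restricted to called cells. Per the file headers, Cell Ranger 5.0.1 made the counts at P0, P14, P28 and P60, 7.0.0 those at P7 and 7.1.0 those of the ganglion. The submitters' processing notes name Seurat without a version and the genome build mm9, whereas all 55450 gene identifiers of the earlier list are in the GENCODE M21 annotation. Whether intronic reads were counted, the aligner's settings and the annotation's release are not given in the sources used here. The 2 software generations list 55450 and 55357 genes, of which the 52081 shared by identifier were used, under the symbols of the first list (2234 have another symbol in the second). The shared genes held between 96.1% and 99.5% of each library's UMIs. Counts on genes that overlap one another, or share reads with a near copy, are uncertain, since the counting rule is not recorded.

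Barcodes with at least 300 genes and 500 UMIs and a mitochondrial share of at most 20% (5% for nuclei) were kept. Doublets were scored with Scrublet as implemented in scanpy 1.11.5. Where its own threshold called under 0.5% of barcodes (0% at P0, 0.0341% in the ganglion), the highest-scoring 8% were removed. The share removed was 8.13%, 4.73%, 2.84%, 4.75%, 2.59% and 8.11% in the order of ages with the ganglion last. Kept barcodes had median depths between 1973 UMIs in the ganglion and 7753 at P7. Depth sets the precision of each level: an exact Poisson interval is given for CPM, an exact Clopper-Pearson interval for shares and an exact conditional interval for ratios of 2 libraries or classes, all at 95%, and a count of 0 is taken to allow 3. These cover counting error only.

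Cells of the 5 nerve libraries were clustered jointly on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden algorithm at resolution 1 (igraph 0.11.9), without batch correction, and the Schwann lineage was clustered again. All genes of the lists described next were kept out of the clustering. Clusters were named from the marker set with the highest mean level relative to the cluster's own libraries, scaled by the spread between clusters. A name needed 3 markers detected in at least 10% of cells and no more markers of another class than of its own among the top 10 genes by fold. A cluster with a median depth under 1/3 of that of its libraries and no marker of its own class among those genes also stayed unnamed. The markers, the 17 gene lists with 258 genes, the tests, the rule for named genes and the alternatives were chosen before the data were examined. The score minimum (0.2, or 0.5 for neurons), the scaling of scores within a library and the rule that leaves replication-led clusters unnamed were set after the clusters were seen. All the naming rules together left 28.7%, 0.758%, 7.45%, 5.59% and 1.47% of cells unnamed from P0 to P60, and 3.23%, 0.911%, 1.09%, 0.389% and 0.370% of Schwann lineage cells. Names are followed by "-like" since they rest on these markers alone. Ganglion nuclei were clustered and named the same way, and their neurons were clustered again. The unmyelinated classes are NP1, NP2, NP3, PEP, cold and cLTMR, pooled in comparisons with NF.

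For the comparison of Schwann classes, UMIs were summed per library and class and fitted with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, robust quasi-likelihood, model with library and class, n = 5 libraries). Both sums of a library come from the same animals, so the library is the pairing block. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, two-sided, at 0.05. Standard errors (SE) are the log2 fold change without its sign, divided by the square root of that test's F statistic. Lists were tested with camera (preset correlation 0.01, and an estimated one) and fry in limma 3.58.1. DESeq2 1.42.0 served as an alternative. The TMM factors were larger in nmSC-like than in mSC-like cells by a mean log2 of 0.24, which lowers the log2 fold changes of nmSC-like over mSC-like cells by that amount. The number of libraries in which a gene was higher is counted on CPM, without these factors. Between ages, each list's median log2 ratio (pseudocount 1 UMI, members with at least 5 CPM and 10 UMIs at one of the ages) was set against 10000 random lists matched on mean level within 50 ranks, and lists at or beyond percentiles 2.5 and 97.5 are described as outside. CPM are scaled to the UMIs of the class in that library. Log2 ratios of single genes by age carry a pseudocount of 1 UMI, and those of the ganglion 2 UMIs divided between the classes in proportion to their totals, which was set after the results were seen because 1 UMI in each class drew the ratios toward NF. Shares of nuclei with a UMI were also computed after thinning to 1000 UMIs, which left out 34 of 98 NF, 52 of 816 unmyelinated and 606 of 3694 non-neuronal nuclei. Log2 ratios after thinning come from a separate random draw of UMIs, so they need not match these shares.

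The genes followed between Schwann classes are the 12 largest log2 fold changes each way among list genes that passed the test with the same direction in every library, and all class 3 semaphorins and semaphorin receptors. Not every gene picked by this rule is printed or drawn. By age they are the 10 largest ratios each way of P60 to P0 in a class and 5 genes highest at an intermediate age. These needed 50 CPM and 30 UMIs at the higher age and a level there at least that of the library's other cells. Mitochondrial, ribosomal, haemoglobin, sex-specific, dissociation and predicted genes were left out. In the ganglion they are all semaphorin receptors, L1cam, Chl1, Nrcam and the list genes with the 5 largest ratios each way. Other list members given as examples were chosen after their values were seen.

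The comparison of Schwann classes and that of lists by age were tested on simulated data; clustering, shares, single-gene ratios and the ganglion comparison were not. In the comparison of Schwann classes, 89% of 100 genes changed by a log2 of 1 and 100% of 100 genes changed by 2 were recovered among 12594 genes, with 6 false calls. In the comparison of lists by age, a list raised 1.5-fold or 2-fold came out at percentile 100, and 1 and 0 of the 15 other lists lay outside. Apart from the changed genes, simulated libraries shared the same mean levels. The class simulation used 1 dispersion for all genes and the list simulation counting error only. Differences between libraries and shared regulation of genes were therefore absent, and the rates do not cover them. The alternatives were a stricter filter (1000 UMIs, 10% mitochondrial), no doublet removal, resolutions 0.5 and 1.5, list genes kept among the clustering features, each library clustered alone, count splitting, other normalizations, tests and filters, no library term, and each library left out in turn. Counts were handled with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.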

Results

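The data comprised 5 single-cell RNA libraries of mouse sciatic nerve and 1 single-nucleus RNA library of lumbar dorsal root ganglia. The nerve libraries covered postnatal days 0, 7, 14, 28 and 60 (P0 to P60), a period in which non-myelinating Schwann cells enclose small axons in Remak bundles and other Schwann cells myelinate large axons. Each nerve library pooled 13 to 22 C57BL/6 animals of both sexes, and the ganglion library pooled 8 animals at P14. Every age had 1 library, so a difference between ages has no replicate check and carries no p-value, and intervals beside levels and shares (95%, exact) cover counting error only. The libraries held 66542228 UMIs at P0, 101441907 at P7, 64797625 at P14, 63226186 at P28, 60763221 at P60 and 20845972 in the ganglion. Filters kept 48546 of 51726 nerve barcodes and 5317 of 5871 ganglion barcodes.

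The first question was how the Schwann lineage was composed at each age. Cells resembling non-myelinating Schwann cells (nmSC-like) made up 35.6% (34.3 to 36.9) of 5208 Schwann lineage cells at P0, 24.2% (23.3 to 25.1) of 8009 at P7, 46.0% (42.9 to 49.2) of 1012 at P14, 73.2% (71.0 to 75.2) of 1799 at P28 and 84.8% (82.5 to 86.9) of 1081 at P60. Cells resembling myelinating Schwann cells (mSC-like) made up 32.8%, 54.3%, 33.2%, 25.1% and 12.6% at the same ages. At P0 they numbered 1710, but 423 without doublet removal, where 1480 Schwann lineage cells received no name. Cycling Schwann cells were 28.3% of the lineage at P0 and between 0.445% and 3.75% at the later ages, and immature-like cells were 18.4% at P7 and 15.9% at P14. These 2 classes moved with the processing: cycling cells at P0 numbered 1476, but 189 with the strict filter, and immature-like cells at P14 161, but 13 at a Leiden resolution of 1.5 and 19 without doublet removal. Immature-like cells at P0 numbered 2, but 634 at that resolution and 970 when each library was clustered alone. The order P60 above P0 held under each clustering tried, but the difference of 49.3 percentage points came to 13.5 when each library was clustered alone and to 84.9 at a Leiden resolution of 0.5, where 0.192% of the P0 cells were nmSC-like. With each library clustered alone the share was 57.9% at P28 and 41.0% at P60, so the order of these ages turned. The Schwann lineage itself was 57.1% of the kept cells at P0, 74.9% at P7, 11.5% at P14, 13.9% at P28 and 15.4% at P60. The yield of each cell type in dissociation can set all of these shares, and it was not measured.

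Outside the Schwann lineage, the nerve libraries held mesenchymal, perineurial, endothelial, mural and macrophage classes. Endothelial cells numbered 30 at P0 and 2871 at P14, but 171 to 303 at P0 with the strict filter, list genes kept, each library clustered alone or count splitting. A cluster that scored highest for endothelial markers, with 266 cells at P0 and 561 at P14, stayed unnamed by the rule on depth. Perineurial cells numbered 477 at P7, 2156 at P14, 5443 at P28 and 913 at P60. Macrophages numbered 183 at P0 and 1501 at P60. At P0, 28.7% of the kept cells received no name, against 0.758% to 7.45% at the other ages. Within the Schwann classes, different sub-clusters held most cells of a class at different ages. The nmSC-like cells lay in sub-clusters 0 at P0, 9 at P7, 17 at P14, 15 at P28 and 16 at P60, and the mSC-like cells in 1 at P0, in 3, 11 and 12 at P7, and in 14 at P14, P28 and P60.

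The next question was which genes separate the glia of unmyelinated axons from the glia of myelinated axons. In nmSC-like cells the cell adhesion molecules Chl1 and L1cam and the class 3 semaphorins Sema3e, Sema3c and Sema3f were higher than in mSC-like cells. So were most genes of the interstitial matrix list and of the interferon and MHC class I list. Most genes of sterol and fatty acid synthesis, the nodal adhesion genes Gldn and Nfasc, and the semaphorins Sema5a, Sema6c and Sema4g were lower. As whole lists, however, none was called by camera with an estimated correlation. The classes were compared within libraries over the 5 ages, so these differences are paired by library. Of 13363 genes tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2171 were higher and 2145 lower in nmSC-like cells. Among the 12490 genes outside the variable genes of the first clustering of all nerve cells, 1839 were higher and 2046 lower. The variable genes of the later Schwann clustering, which formed the classes, were not left out of this count. Without the library term 904 were higher and 844 lower, and without the P14 library 1627 were higher and 1413 lower.

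**Figure D1:**
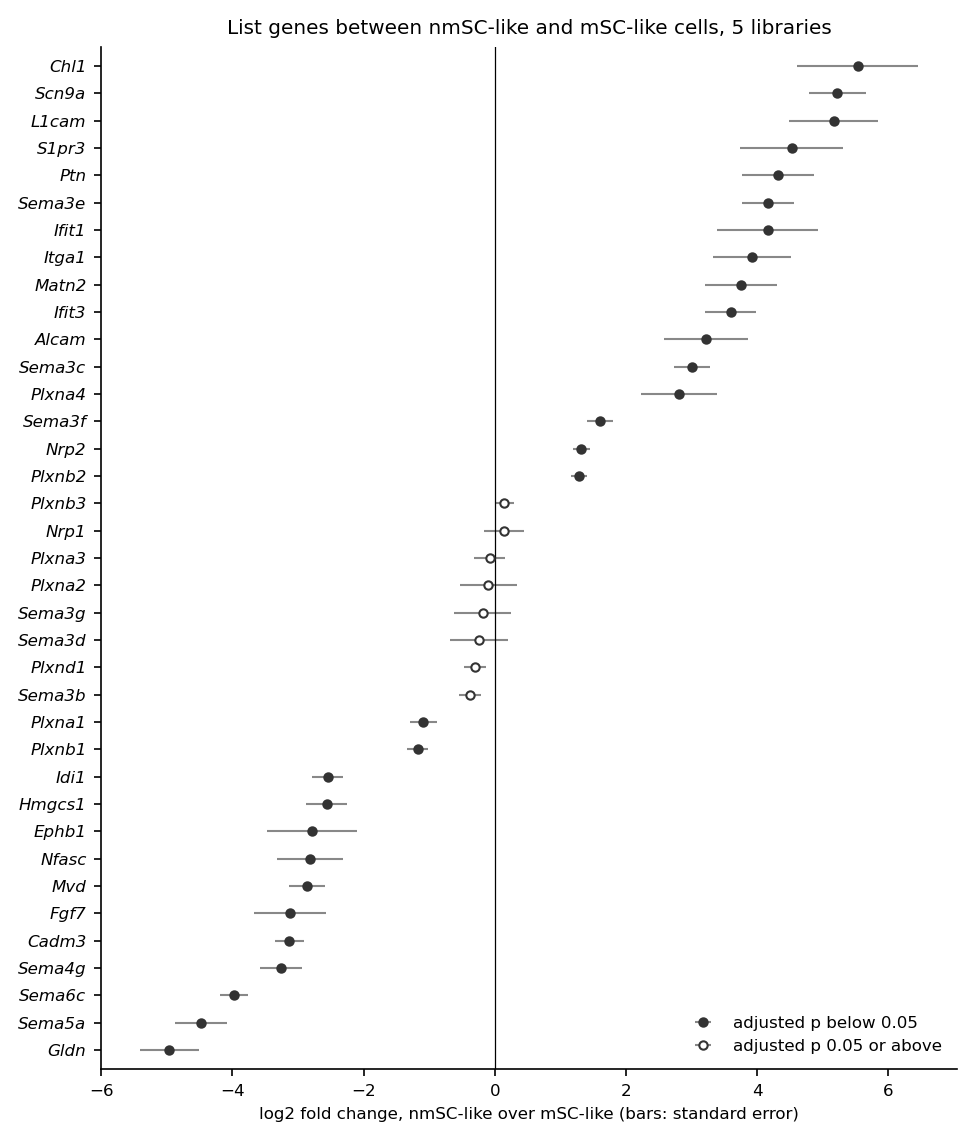
Log2 fold change of nmSC-like over mSC-like cells (horizontal axis) for genes of the fixed lists named in the text (vertical axis). Bars are standard errors derived from the test's F statistic in the fit of 5 libraries. Filled points passed an adjusted p of 0.05, and Sema3b lies at -0.38 among the open points.

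The adhesion list, which holds molecules of contacts between axons and glia and between axons, had 13 members higher and 4 lower among 19 tested, with the same counts when adjusted over the list alone. Chl1 was higher by a log2 fold change of 5.53 (SE 0.921), with an adjusted p of 0.00464 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and was higher in 5 of 5 libraries. L1cam was higher by 5.16 (SE 0.674, adjusted p = 0.00182 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), also in 5 of 5 libraries. Alcam, an immunoglobulin superfamily adhesion protein, passed the same test at 3.22 (SE 0.645). In the other direction, Gldn, which clusters sodium channels at nodes of Ranvier, stood at -4.96 (SE 0.448), Cadm3 at -3.13 (SE 0.223) and Nfasc, whose glial form lies at paranodes, at -2.82 (SE 0.500). Without P0, Chl1 stood at 6.57, L1cam at 6.12 and Alcam at 4.20, and Alcam at 2.62 without P7 and at 4.04 at a Leiden resolution of 0.5. The fit at that resolution also lacked P0, which had too few nmSC-like cells there. Without the library term, Alcam (1.67) and Nfasc (-2.37) no longer passed the test, with adjusted p of 0.338 and 0.107 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

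Of 6 class 3 semaphorins tested, 3 were higher in nmSC-like cells and 0 lower, both over all genes and adjusted over the list alone. Sema3e was higher by 4.16 (SE 0.394), Sema3c by 3.01 (SE 0.272) and Sema3f by 1.60 (SE 0.20), each in 5 of 5 libraries. Sema3e stood at 4.86 without P0, 4.91 without doublet removal, 4.75 at a Leiden resolution of 1.5 and 5.21 without the library term. Without the library term Sema3f (1.81) had an adjusted p of 0.112 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Sema3b, the semaphorin named in the study's title, had a log2 fold change of -0.38 (SE 0.166), an adjusted p of 0.116 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and a higher level in nmSC-like cells in 2 of 5 libraries by CPM and in 0 of 5 after the TMM factors. By CPM its mean log2 ratio over the libraries was -0.14. It therefore did not pass the test, and its adjusted p ranged from 0.0219 to 0.619 over the alternatives. The values of Sema3d (-0.24) and Sema3g (-0.18) did not pass either, but Sema3d without doublet removal (1.49) and Sema3g without P7 (-0.76) had adjusted p of 0.03997 and 0.0492 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among the other semaphorins 3 members were higher and 5 lower of 12 (4 and 5 adjusted over the list alone), with Sema4d at 2.04, Sema7a at 1.46, Sema5a at -4.48 (SE 0.390), Sema6c at -3.98 (SE 0.213) and Sema4g at -3.25 (SE 0.321).

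Semaphorin receptors went both ways, with 3 higher and 2 lower of 10 tested. Plxna4 was higher by 2.81 (SE 0.579), Nrp2 by 1.32 (SE 0.128) and Plxnb2 by 1.28 (SE 0.127), whereas Plxnb1 was at -1.18 (SE 0.156) and Plxna1 at -1.09 (SE 0.206). Plxna4 stood at 2.01 without P7, 3.68 with the strict filter and 3.42 both at a Leiden resolution of 1.5 and with each library clustered alone. Without the library term Plxnb1 (-1.30) had an adjusted p of 0.0780 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The log2 fold changes of Nrp1 (0.14), Plxnb3 (0.14), Plxna3 (-0.08), Plxna2 (-0.10) and Plxnd1 (-0.30) did not pass the test. Genes that transmit semaphorin signals gave 3 higher (Farp1 2.87, Dpysl5 1.76, Dpysl3 1.66) and 3 lower (Fyn -1.57, Mical3 -1.12, Mical1 -0.87) of 14. These receptor and transduction counts were the same when adjusted over the list alone.

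Of the interstitial matrix list, 12 of 14 were higher in nmSC-like cells and 0 lower (14 and 0 adjusted over the list alone), among them Matn2, a filament-forming matrix protein, at 3.75 (SE 0.551), Tnc at 3.10 and Postn at 2.45. Basal lamina genes and their receptors gave 10 higher and 2 lower of 23 (13 and 2 adjusted over the list alone), led by Itga1, a collagen and laminin receptor, at 3.92 (SE 0.594), with Nid2 at 2.03, Lama4 at 1.22 and, in the other direction, Utrn at -1.89. Genes of axonal signal reception gave 5 higher and 1 lower of 11 (6 and 1 adjusted over the list alone). The higher ones included S1pr3, a receptor of sphingosine 1-phosphate, at 4.52 (SE 0.792), Lgi4 at 2.19 and Notch1 at 1.52. Without P0, Itga1 stood at 4.70 and S1pr3 at 5.43. At a Leiden resolution of 0.5, where the fit also lacked P0, Itga1 stood at 4.53.

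Sterol and fatty acid synthesis was the list with the most members lower in nmSC-like cells. There 0 of 23 were higher and 21 lower, or 1 and 21 adjusted over the list alone. Mvd stood at -2.86 (SE 0.280), Hmgcs1 at -2.56 (SE 0.315) and Idi1 at -2.55 (SE 0.241), all enzymes of the mevalonate pathway. Among transcription factors of Schwann cells, 5 were higher and 3 lower of 14, with Hey2 at 2.83 and Sox11 at 2.16 on one side and the promyelinating factors Egr2 at -1.95 and Pou3f1 at -1.86 on the other. Trophic factors gave 4 higher and 3 lower of 13 (5 and 3 adjusted over the list alone), from Ptn, a heparin-binding growth factor, at 4.32 (SE 0.555) to Fgf7 at -3.12 (SE 0.550). Other guidance genes gave 8 higher and 3 lower of 18 (9 and 3 adjusted over the list alone), from Epha7 at 2.86 to Ephb1 at -2.79 (SE 0.683). Ptn stood at 4.93 without P0 and Ephb1 at -3.69 with DESeq2. Fgf7 stood at -3.83 at a Leiden resolution of 0.5, where the fit also lacked P0. Without P7, Ephb1 (-2.32) had an adjusted p of 0.0587 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

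Genes of interferon responses and MHC class I gave 8 higher and 0 lower of 10, with Ifit1 at 4.16 (SE 0.769), Ifit3 at 3.60 (SE 0.391) and H2-D1 at 2.00. Ifit1 stood at 6.09 without P0, 3.47 without P7, 5.16 without doublet removal and 5.07 with DESeq2, and Ifit3 at 4.82 without the library term. At a Leiden resolution of 0.5, where the fit also lacked P0, Ifit1 stood at 5.66. The immediate early and heat shock genes, which mark stress during dissociation, gave 6 higher and 0 lower of 15 (7 and 0 adjusted over the list alone), with Ier3 at 1.58, Atf3 at 1.45 and Egr1 at 1.07. DNA replication genes gave 5 higher and 0 lower of 14 (7 and 0 adjusted over the list alone), with Rrm2 at 1.37. Both members tested of the nociceptor channel list were higher, the sodium channel gene Scn9a at 5.22 (SE 0.433) and the potassium channel gene Kcnq5 at 2.42. Scn9a stood at 6.35 without P0, 5.84 with the strict filter and 5.86 with each library clustered alone. Of 4 nodal and large-fibre channel genes 1 was higher (Scn8a at 1.51) and 1 lower. Adjusted over the list alone, the counts for transcription factors, interferon genes, nociceptor channels and nodal channels were the same.

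Against all other genes, camera with its preset correlation of 0.01 called 9 of the 17 lists. The adjusted p was 1.21e-09 for sterol synthesis (lower), 4.08e-06 for interstitial matrix, 0.00252 for interferon and MHC class I, 0.00317 for immediate early genes, 0.00509 for basal lamina, 0.00648 for axonal signal reception, 0.00877 for DNA replication, 0.00930 for adhesion and 0.0119 for nociceptor channels (all higher). With an estimated correlation 0 lists were called, and each of these 9 had an adjusted p of 0.392. Class 3 semaphorins had an adjusted camera p of 0.106. The fry test, which asks whether members move on balance one way without comparing them with other genes, called 14 of the 17 lists. With 2171 genes higher and 2145 lower of 13363, a low fry p does not set a list apart from other genes. Fry gave class 3 semaphorins an adjusted fry p of 0.00361 and adhesion 0.0609. Signal transduction (down), axonal signal reception, interstitial matrix and nociceptor channels (all up) had the same fry value as class 3 semaphorins. The mixed form of fry, which asks for change in either direction, called 16 lists and gave adhesion 0.00128. Signs differed for the other semaphorins (median log2 0.05, mean -0.60, camera down), for signal transduction (median -0.14, mean 0.01, camera down), for transcription factors (camera up, fry down) and for nodal channels (median -0.01, mean -0.53, camera down, fry up).

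How Sema3b changed over the window in which Remak bundles form was the next question. In nmSC-like cells Sema3b stood at 295 CPM (286 to 305) at P0, 242 (232 to 252) at P7, 581 (542 to 622) at P14, 655 (625 to 685) at P28 and 616 (588 to 644) at P60. Its level at P60 was 2.08 times that at P0 (1.97 to 2.20), and its level at P14 was 2.40 times that at P7 (2.22 to 2.60). In mSC-like cells it stood at 289 CPM (281 to 297) at P0, 388 (383 to 394) at P7, and 614 (579 to 651), 673 (636 to 712) and 579 (523 to 639) at P14, P28 and P60. From P0 to P7 the classes differed, with a ratio of 0.818 (0.776 to 0.862) in nmSC-like and 1.35 (1.30 to 1.39) in mSC-like cells. Immature-like Schwann cells stood at 410 CPM (398 to 422) at P7 and 711 (657 to 769) at P14, above both classes at these ages. In the other nerve classes Sema3b ranged from 4.53 to 27.9 CPM in macrophages, from 5.48 to 28.8 in endothelial cells and from 8.07 to 17.9 in mural cells. In perineurial cells it went from 33.3 at P7 to 97.2 at P60. Mesenchymal cells held 25.8 at P0, 103 at P28 and 93.7 at P60. A higher level at later ages was therefore not limited to Schwann cells. Median-of-ratios scaling put the ratio of P60 to P0 in nmSC-like cells at 1.97 and that of P14 to P0 at 1.66, against 1.97 for the latter by totals. With this scaling the ratios of P7 to P0 and of P14 to P7 were 0.893 and 1.86 in nmSC-like and 1.69 and 1.16 in mSC-like cells.

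**Figure D2:**
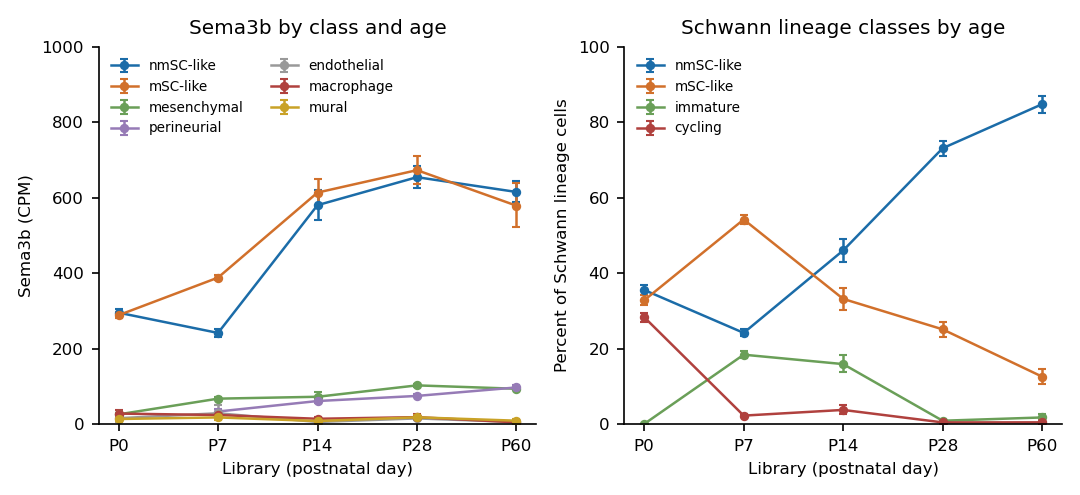
Left, Sema3b in CPM by nerve class at each age, with exact Poisson intervals and without immature-like Schwann cells. Right, percent of Schwann lineage cells in each Schwann class, with exact binomial intervals. Sema3b in nmSC-like cells stands at 295 CPM at P0 and 616 at P60, and the nmSC-like share at 35.6% and 84.8%.

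The other class 3 semaphorins of nmSC-like cells took different courses. Sema3e went from 11.5 CPM at P0 to 98.2 at P14 and 119 at P60, a ratio of P60 to P0 of 10.4 (8.50 to 12.7). Sema3f stood at 5.02 CPM at P0 and 29.1 at P60, Sema3c at 119 and 107, and Sema3g at 21.1 and 6.20. Among the receptors, Nrp2 stood at 325 CPM at P0, 761 at P14 and 440 at P60, and Nrp1 at 49.9, 136 and 13.1.

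Class 3 semaphorins, with 5 members measured, had a median log2 ratio of P60 over P0 of 1.06 in nmSC-like cells. It lay at percentile 98.4 of 10000 random lists matched on level. This median is the value of Sema3b itself, with 3 members at least 2-fold higher and 1 at least 2-fold lower. Other semaphorins had 0.93 at percentile 97.8. The corresponding values in mSC-like cells were 1.01 at percentile 84.0 and 0.87 at percentile 97.1, which lie within the central 95% of random lists. There too the class 3 median is the value of Sema3b. Semaphorin receptors had medians of -0.06 (percentile 36.7) and 0.21 (49.1), and signal transduction 0.01 (52.1) and 0.23 (73.6), in nmSC-like and mSC-like cells. Between P7 and P14 the class 3 semaphorins moved by 1.27 (percentile 99.4) in nmSC-like and 1.55 (99.3) in mSC-like cells, and the receptors by 1.17 (99.95) and 1.70 (100). The class 3 value in nmSC-like cells is again that of Sema3b. Such movement was common over this step. Of 16 lists, 10 lay outside on the higher side and 3 on the lower in nmSC-like cells, and 5 and 1 in mSC-like cells. Basal lamina genes, for example, moved by 1.30 (percentile 100) in nmSC-like cells, where the median over all genes was 0.31. The P7 library was processed with a later software version than the other nerve libraries, and the immediate early list moved by -2.15 in nmSC-like and -2.49 in mSC-like cells over the same step. With P14 in place of P60, a comparison within 1 software version that was added after seeing the data, class 3 semaphorins in nmSC-like cells had 0.98 at percentile 97.2, within the central 95%. They also lay within it with each library clustered alone (1.08, percentile 96.1) and among members with at least 20 CPM (1.06, percentile 91.4), as did other semaphorins in the latter case (percentile 96.9).

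Which other programmes differed between newborn and adult Schwann cells was asked with the same lists. In mSC-like cells sterol and fatty acid synthesis was higher at P60, with a median log2 ratio of 1.84 (percentile 100) and 17 of 23 members at least 2-fold higher, including Lss at 2.61. The median in nmSC-like cells was 0.69 (percentile 99.99), with Srebf1, a regulator of fatty acid synthesis, at 2.45. Adhesion genes in mSC-like cells had a median of -0.85 (percentile 0.01), with Alcam at -4.91 and Ncam2 at -4.61, whereas Nfasc stood at 3.85 and Cadm3 at 2.39; at a Leiden resolution of 0.5 the median was -0.17 (percentile 9.56), within the central 95%. Interstitial matrix genes in mSC-like cells had a median of -1.07 (percentile 0.05), with Postn at -4.46 and Tnc at -4.28, but 0.078 (percentile 63.1) for P14 over P0. DNA replication genes in nmSC-like cells had a median of -1.06 (percentile 0), with Mcm5 at -2.77 and Mcm2 at -1.93, but -0.13 (percentile 32.6) among members with at least 20 CPM. Transcription factors in mSC-like cells had a median of 0.61 (percentile 98.1), with Nab1 at 2.91 and Sox11 at -3.63, but -0.32 (percentile 22.5) for P14 over P0.

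Interferon and MHC class I genes had a median log2 ratio of 3.34 (percentile 100) in nmSC-like cells, with Ifit3 at 5.08, H2-D1 at 4.76 and H2-K1 at 4.49, and 1.31 (percentile 99.96) in mSC-like cells. The immediate early and heat shock list was also higher at P60, by 2.94 in nmSC-like and 3.32 in mSC-like cells (percentile 100 in both). For P14 over P0 in mSC-like cells the interferon list (0.45, percentile 85.5) and the immediate early list (0.33, percentile 84.5) lay within the central 95%. Of 16 lists with at least 3 members measured, 6 lay outside the central 95% of random lists in nmSC-like cells and 6 in mSC-like cells. Besides semaphorin receptors and signal transduction, the lists within it were adhesion (0.42, percentile 96.4, with L1cam at 1.60 and Chl1 at 2.64), axonal signal reception (0.28, 84.7), basal lamina (-0.24, 30.5), interstitial matrix (-0.14, 43.6), trophic factors (0.11, 53.2), other guidance (-0.02, 38.3), transcription factors (0.29, 91.4) and nodal channels (1.94, 96.8) in nmSC-like cells. In mSC-like cells they were, besides the semaphorin lists, axonal signal reception (-0.32, 7.08), basal lamina (-0.35, 14.02), DNA replication (0.22, 51.3), trophic factors (0.41, 75.4), other guidance (0.07, 30.5) and nodal channels (1.24, 96.5). The median over all genes was 0.06 in nmSC-like and 0.14 in mSC-like cells.

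**Figure D3:**
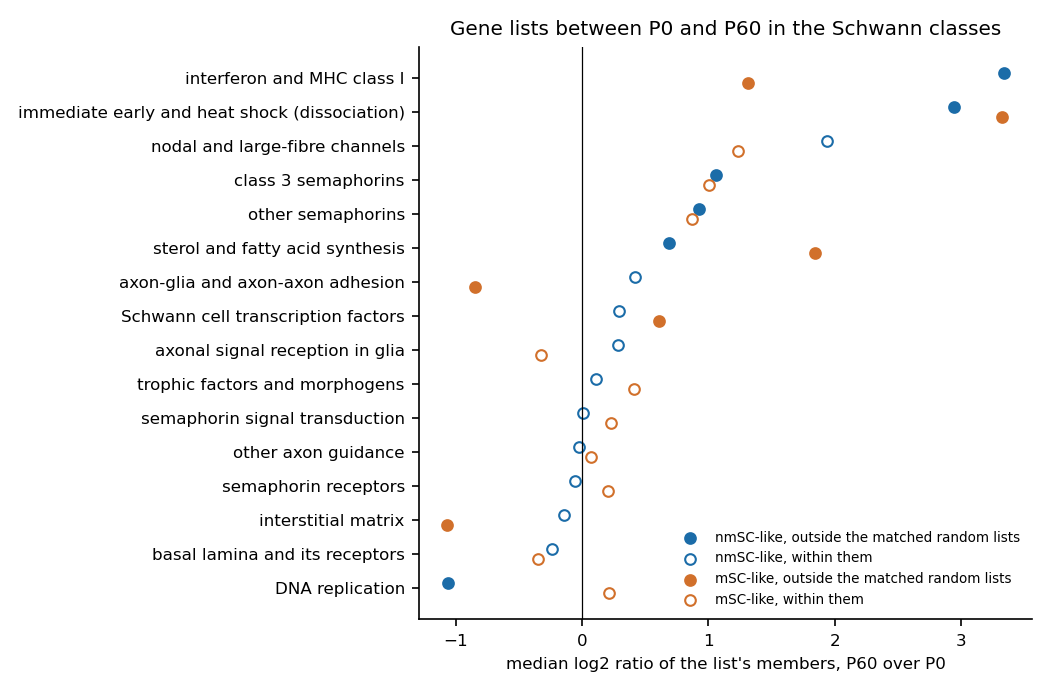
Median log2 ratio of P60 over P0 (horizontal axis) for each gene list (vertical axis) in nmSC-like and mSC-like cells, 1 library per age. Filled points lie outside the central 95% of matched random lists, as does sterol synthesis at 1.84 in mSC-like and 0.69 in nmSC-like cells.

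Among single genes in nmSC-like cells, C4b, Serpina3n and C3 had the largest ratios of P60 to P0. The complement components C4b and C3 stood at 1775 and 918 CPM at P60 against 0.167 CPM (2 UMIs) and 0.418 CPM at P0, ratios of 10612 (2936 to 87652) and 2196 (940 to 6767). Serpina3n, a protease inhibitor, stood at 397 against 0.0836 CPM (1 UMI), a ratio of 4745 (850 to 187562). Aldh1a1, which makes retinoic acid, had a ratio of 1264 (613 to 3148), Dusp26 of 715 (127 to 28380, 1 UMI at P0), the chaperone gene Clu of 248 (119 to 620), Gpnmb of 153 (88.6 to 289), the complement protease gene C1ra of 145 (83.9 to 274), Cyp2d22 of 104 (73.5 to 152) and Chrdl1, a BMP antagonist, of 99.0 (58.2 to 183). Of these, Aldh1a1, Serpina3n, C3, Gpnmb, Clu and C4b led sub-cluster 16, which held 78.1% of the nmSC-like cells at P60 and took 716 of its 742 cells from that library.

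Among genes lower at P60 in nmSC-like cells, Col9a2 was lower by 28.6-fold (13.1 to 78.3), Tnc by 22.9-fold (13.4 to 43.2), Col14a1 by 19.98-fold (15.5 to 26.3) and the D-type cyclin Ccnd2 by 12.4-fold (9.89 to 15.8). Atp10b (24.5-fold), Ddah1 (16.9-fold), Dab1 (16.5-fold), the transcription factor gene Sox5 (13.1-fold), the glutamate receptor gene Gria2 (12.4-fold) and Ntm (11.6-fold) were also lower; with the strict filter the log2 ratios of Gria2 and Ntm were -6.95 and -5.79, against -3.59 and -3.51. Highest at an intermediate age were Tenm1 and Srd5a1 at P14 (69.2 and 158 CPM), Rtbdn at P28 (56.0 CPM), and Timm23 and Tmem254a at P7 (111 and 218 CPM). The last pair was also higher in the other nerve classes at P7, the library with the later software version.

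In mSC-like cells the largest ratios of P60 to P0 belonged to Dusp26 at 109 (59.1 to 218), the metallothionein gene Mt3 at 85.3 (69.6 to 105), Tmcc3 at 80.01 (47.2 to 142), the transcription factor gene Klf2 at 72.6 (60.3 to 87.9, with 9.01, 518, 63.6, 193 and 655 CPM from P0 to P60, in each step the direction of the immediate early list), Fam81a at 63.1, Fam178b at 60.5, Chrdl1 at 54.1, Sult1a1 at 47.8, Drp2 at 45.4 and the carbonic anhydrase gene Car14 at 32.7. Mt3, Fam178b and Drp2 are leading genes of sub-cluster 14, which held the mSC-like cells from P14 on, and Drp2 was one of the markers of the class. Lower at P60 were the cyclin genes Ccnd1 at 44.3 against 1033 CPM (23.3-fold, 16.3 to 34.6) and Ccnd2 at 2 UMIs against 380 CPM (128-fold, 35.6 to 1061), and the cell cycle inhibitor gene Cdkn1c at 127 against 4612 CPM (36.3-fold, 29.4 to 45.4). Gria2 (76.2-fold, 21.1 to 629), Hmga2 (68.0-fold, 12.2 to 2686), Ntm (55.6-fold, 19.01 to 270) and Tmem45a (36.1-fold, 6.46 to 1426) were lower with 1 to 3 UMIs at P60. The endothelin receptor gene Ednrb, a marker of the immature class, was lower by 25.7-fold and Fbln5 by 25.9-fold, and Smim5, with 61.4 CPM at P0 and 0 UMIs at P60, was at least 13.9-fold lower against a floor of 3 UMIs. Without doublet removal the log2 ratios of Gria2, Ntm and Smim5 were -3.51, -2.75 and -2.07, against -5.67, -5.38 and -5.38. Highest at an intermediate age were H2-DMa and Chst2 at P7 (81.2 and 67.7 CPM), both leading genes of the P7 sub-cluster 12, Col5a3 and Rab7b at P14 (440 and 82.4 CPM) and Lrrtm2 at P28 (54.0 CPM).

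Which sensory neurons carry the receptors of class 3 semaphorins was asked in the P14 ganglion. Of the neuronal nuclei, 98 resembled large neurons with mostly myelinated axons (NF), and 450 received no name. The other 816 were assigned by markers to 6 classes grouped here as unmyelinated, although axons were not examined. The clusters named NF and PEP each had 0 markers of their class among their top 10 genes. Plxna4 was higher in the unmyelinated classes together, at 340 against 153 CPM in NF nuclei (ratio 2.22, 1.77 to 2.84), but its log2 ratio was 0.13 without doublet removal. Nrp1 was higher in NF nuclei, at 250 against 157 CPM (ratio 1.59, 1.31 to 1.92), as were Plxna2, at 273 against 159 CPM, and Plxna1, at 26.9 against 5.94 CPM (4.53-fold, from 13 UMIs in NF). After thinning to 1000 UMIs, Plxna1 was in 0 of 64 NF and 10 of 764 unmyelinated-class nuclei (1.31%), and Nrp1 in 14.1% (6.64 to 25.0) and 12.7% (10.4 to 15.3), intervals that overlap. The ratio of unmyelinated to NF nuclei was 1.59 (0.853 to 3.36) for Nrp2 and 1.52 (0.635 to 4.76) for Plxna3, intervals that include 1. Nrp2 turned to a log2 ratio of -1.44 without doublet removal and to -0.29 after thinning.

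**Figure D4:**
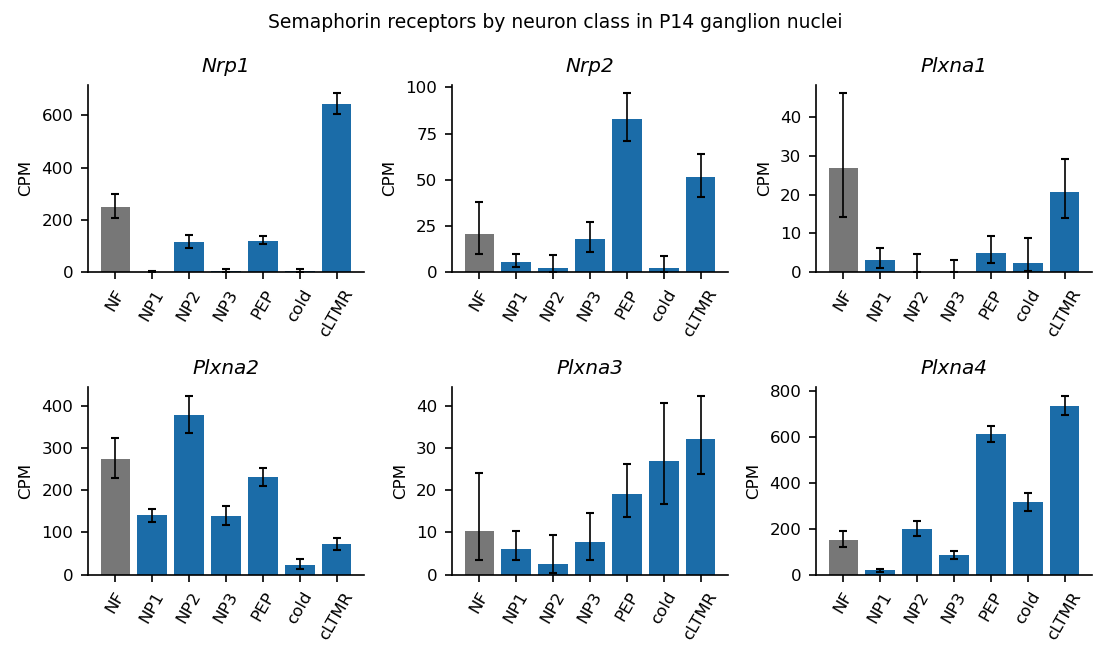
Level of 6 semaphorin receptor genes in CPM (bars, from 0) by neuron class in 1 P14 ganglion library, with exact Poisson intervals; NF is grey and the 6 unmyelinated classes are blue. Nrp1 and Plxna4 reach 642 and 737 CPM in cLTMR nuclei.

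The unmyelinated classes differed from one another more than their sum showed. C-fibre low-threshold mechanoreceptors (cLTMR) had 642 CPM of Nrp1 and 737 of Plxna4, and peptidergic neurons (PEP) had 121 and 614, together with 83.1 CPM of Nrp2. Mrgprd-type neurons (NP1) had 2.64 CPM of Nrp1 and 18.1 of Plxna4, Sst or Nppb-type neurons (NP3) had 5.97 and 86.1, and Trpm8-type neurons (cold) had 4.87 and 315. Mrgpra3 or Mrgprb4-type neurons (NP2) had 115 CPM of Nrp1, 199 of Plxna4 and the highest Plxna2 of the neuron classes, 378 CPM. After thinning to 1000 UMIs, 51.1% (42.4 to 59.8) of cLTMR nuclei and 14.1% (6.64 to 25.0) of NF nuclei held a UMI of Nrp1, against 1.205% (0.146 to 4.28) in NP1 and 12.5% (11.4 to 13.8) in non-neuronal nuclei, among which endothelial nuclei had 1016 CPM. For Plxna4 the thinned shares were 51.9% (43.1 to 60.5) in cLTMR, 37.1% (30.4 to 44.1) in PEP and 12.5% (5.55 to 23.2) in NF, against 4.53% (3.83 to 5.33) in non-neuronal nuclei. Median depths were 1360.5 UMIs in NF, 8529 in the unmyelinated classes and 1839 in non-neuronal nuclei, and before thinning 27.6% of NF and 74.4% of cLTMR nuclei held a UMI of Nrp1, and 26.5% and 75.0% one of Plxna4.

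Of the other receptors, Plxnd1 had 47.4 CPM in the unmyelinated classes and 0 UMIs in NF, at least 7.64-fold higher against a floor of 3 UMIs, with 68.7 CPM in NP1. Non-neuronal nuclei had 48.9 CPM, and after thinning Plxnd1 was in 4.32% (2.99 to 6.01) of the unmyelinated-class nuclei, 4.53% (3.83 to 5.33) of the non-neuronal nuclei and 0 of 64 NF nuclei (interval to 5.60%). Plxnb1 (ratio 2.93, 0.503 to 118), Plxnb2 (6.30, 1.11 to 251) and Plxnb3 (0.338) had too few UMIs in NF for a narrow interval. Among adhesion partners, L1cam was higher in the unmyelinated classes (157 against 93.1 CPM, ratio 1.68, 1.25 to 2.32), Nrcam was higher in NF (166 against 61.0 CPM, 2.71-fold, 2.12 to 3.44) and Chl1 had 110 against 99.3 CPM (ratio 1.11, 0.832 to 1.52). After thinning, in a random draw apart from that of the shares, the log2 ratios were -0.16 for L1cam and -0.022 for Chl1. Of all list genes, the largest ratios in favour of the unmyelinated classes were those of the nociceptor channel genes Scn10a (17.5, 12.0 to 26.6), Trpv1 (12.7) and Scn11a (10.2), followed by Sox4 (4.95) and Tead1 (4.56). Without doublet removal the log2 ratios of Scn10a and Tead1 were 1.97 and 0.068, and after thinning that of Scn11a was 1.90. In favour of NF were the guidance gene Slit2 (35.0-fold, 29.6 to 41.5), the adhesion gene Nlgn1 (19.3-fold), the potassium channel gene Kcna1 (15.1-fold), Col4a2 (13.5-fold) and Sema3d (13.5-fold). Looked up after these genes were found, the same RNAs also stood in other ganglion cells, Kcna1 at 1012 CPM in Schwann nuclei, Nlgn1 at 892 in satellite glia, and Slit2, Col4a2 and Sema3d at 532, 274 and 289 in mesenchymal nuclei, and the satellite glia marker Apoe stood at 1409 CPM in NF nuclei against 735 in the unmyelinated classes.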

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

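The tests of dissociation and free RNA for the interferon genes, and of software version and dissociation for Sema3b, were chosen after the results were seen, as was the rule that found the 4 genes of the P7 library.

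In 2 lists the change from P0 to P60 had opposite signs in nmSC-like and mSC-like cells and lay outside the random lists in 1 of them, although the differences themselves were not tested. DNA replication genes had a median log2 ratio of -1.06 (percentile 0) in nmSC-like cells and 0.22 (percentile 51.3) in mSC-like cells, a difference of -1.27, though the nmSC-like median was -0.13 among members with at least 20 CPM. Adhesion genes had 0.42 (percentile 96.4) and -0.85 (percentile 0.01), a difference of 1.26. Interferon and MHC class I genes stood further apart, at 3.34 and 1.31, with the same sign.

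Some other classes of the ganglion held more of Sema3b, Sema3c or Sema3d than NF nuclei and the pooled unmyelinated nuclei. Sema3b stood at 148 CPM (124 to 175) in Schwann nuclei and 60.5 CPM (53.8 to 67.8) in satellite glia, against 6.21 in NF and 3.38 in unmyelinated-class nuclei. Sema3c stood at 197 CPM (169 to 229) in Schwann nuclei, 199 CPM (187 to 212) in satellite glia and 866 CPM (809 to 926) in mesenchymal nuclei, against 18.6 and 40.5 in the neurons. Sema3d stood at 289 CPM (256 to 324) in mesenchymal nuclei, against 103 in NF and 7.69 in unmyelinated-class nuclei. This did not hold for every gene or class, since Sema3d stood at 3.38 CPM in Schwann nuclei and 7.13 in satellite glia, and Sema3f at 19.2, 11.4 and 5.12 CPM in Schwann nuclei, satellite glia and mesenchymal nuclei, against 49.7 in NF nuclei.

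Sema3b in nmSC-like cells stood at 242 CPM at P7 and 581 CPM at P14. Within one software version the ratio of P14 to P0 was 1.97 (1.82 to 2.12), which argues against the later version of the P7 library as the whole cause. Stress during dissociation that raises Sema3b is argued against by the step from P7 to P14, which also crosses software versions. There Sema3b had a ratio of 2.40 (2.22 to 2.60) and the immediate early list a median log2 ratio of -2.15. Stress that lowers Sema3b, as the whole cause, is argued against only by the step from P14 to P28. There Sema3b had a ratio of 1.13 (1.04 to 1.23) and the list 1.96. From P0 to P7 the values were 0.818 and 2.54, and from P28 to P60 0.940 (0.881 to 1.003) and 0.36. In these steps, as from P7 to P14, the directions were opposite, so such stress stays open for them. Scaling by the median of ratios left P14 over P0 at 1.66, which argues against the scaling by totals as the whole cause. Development between P0 and P14 remains open as a hypothesis, untested because each age had 1 library.

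Interferon and MHC class I genes were higher with age in nmSC-like cells. From P7 to P14, between which the software version also differs, the median log2 ratio of the 10 genes was 0.85, with 10 of 10 above 0, while the immediate early list had -2.15 with 15 of 15 below 0, which argues against stress during dissociation as the cause of that step. In the 3 other steps both lists moved the same way (0.86 and 2.54 from P0 to P7, 1.09 and 1.96 from P14 to P28, 0.28 and 0.36 from P28 to P60), so stress stays open there, beside age, which is untested with 1 library per age. At P60 the median ratio of the genes' level in nmSC-like cells to that in the library's other cells was 1.66, or 59.6 times the 0.0279 of the abundant genes of those other cells (highest 0.392), which argues against free RNA as the cause. C3, C4b, C1ra, Clu and Serpina3n were left out of these tests, since the rule that named them required a level at P60 at least that of the other cells.

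Plac9a, Tmem254a, Timm23 and D930016D06Rik were at least 3 times higher at P7 than at every other age in each nerve class examined, and the same rule found 0 genes at P0, P14, P28 and P60. All 4 (100%, interval from 39.8%) were also at least 3 times higher in Schwann nuclei of the ganglion, whose software is likewise later, than in Schwann cells of the P14 nerve, against 2.01% of 3239 other genes. The software or gene list of the P7 library may thus be the source, but 4 genes are too few to set the share above 50%, and the ganglion also differs in being nuclei. Overlap with genes missing from the later list was found for 0 of 4, a ratio of 0 (interval to 15.2) to the 3.98% of 5282 other genes, which leaves reads shared with those genes open. No biological explanation was tested, since age and version cannot be told apart at P7.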

How the results depend on the processing

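The comparisons with P14 in place of P60, and the count of splits, were chosen after the results were seen. Over the alternatives, counts of genes higher and lower in nmSC-like cells lay within 1.5 times the reported ones, except without the library term as a replicate block (904 and 844) and for the lower genes without P14. Leaving out each library in turn gave 1585 to 2176 higher and 1413 to 2106 lower genes, and a Sema3b log2 fold change of -0.47 to -0.20, always with an adjusted p above 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (0.106 to 0.242). Sema3b passed that test without doublet removal (-0.49, adjusted p = 0.0302) and without the low-count filter (-0.43, adjusted p = 0.0219), within a range up to 0.619. Exchanging the classes within libraries makes 16 splits, too few for a share under 0.05: 1 split, the real one, gave 4316 genes, and the highest of the others gave 0. Of 601 values of the 38 other genes followed between the classes, 582 kept their direction and side of the threshold, 5 no longer passed, 1 newly passed in its direction (Sema3g, -0.76 without P7) and 13 turned, none of these from a called value. Of these, Sema3d without doublet removal passed in the new direction (adjusted p = 0.03997 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The turned values were Plxna2 (0.27) with the strict filter; Sema3d (1.49) without doublet removal; Sema3g (0.59) at resolution 0.5; Plxna2 (0.12) and Sema3d (0.27) with each library clustered alone; and Plxna3 (0.12) without the replicate block. The fit at resolution 0.5 also lacked P0, which had too few nmSC-like cells there. Leaving out each library in turn gave -0.12 to 0.45 for Nrp1, -0.30 to 0.28 for Plxna2, -0.24 to 0.051 for Plxna3 and -0.76 to 0.13 for Sema3g.

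The difference in nmSC-like share between P60 and P0, 49.3 percentage points, was 41.9 with the strict filter, 45.6 without doublet removal, 84.9 at resolution 0.5, 39.95 with list genes kept in the clustering and 13.5 with each library clustered alone. The log2 ratio of Sema3b between P60 and P0, 1.06, was 1.16 with list genes kept, 0.98 with median-of-ratios scaling and 0.97 for P14 over P0. Between 12 and 15 lists by age lay outside the random lists under the alternatives with values in both classes, and of 102 values of the 12 lists, 92 kept their call, 8 no longer passed and 2 turned, both for P14 over P0 in mSC-like cells (interstitial matrix 0.078, transcription factors -0.32). At resolution 0.5 P0 had too few nmSC-like cells for nmSC-like values by age. Of 328 values of genes named by age 279 lay within their intervals and 0 turned.

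In the ganglion, without doublet removal the log2 ratios were -1.44 for Nrp2, -1.06 for Plxna2, 0.13 for Plxna4 and -0.64 for Chl1. As means per nucleus they were -0.39 for Nrp2, -0.24 for Plxna2 and -0.33 for Chl1. After thinning they were -0.29 for Nrp2, 1.39 for Plxna1, 1.66 for Plxnb3, -0.16 for L1cam and -0.022 for Chl1. In that random draw 0 UMIs of Plxna1 and Plxnb3 were left in NF and 3 and 4 in the unmyelinated classes. The shares of thinned nuclei came from a separate random draw, in which more unmyelinated-class nuclei held Plxna1. Depth limits these values, since the NF nuclei held 10 UMIs of Nrp2 and 5 of Plxna3. Where a value changed, the cause was not tested.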

Other observations

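Other cell types of the nerve also differed between P0 and P60, with 1 library per age and intervals that cover counting error only. Mesenchymal cells at P60 held Inmt at 251 CPM and Cpxm2 at 217 CPM against 0 UMIs at P0, at least 601-fold and 520.2-fold higher against a floor of 3 UMIs. C3 (726 CPM, ratio 1739, 595 to 8431), Myoc (1374 CPM, ratio 1097, 578 to 2398) and the chemokine gene Cxcl13 (90.1 CPM, ratio 647, 116 to 25578, 1 UMI at P0) were also higher. Lower at P60 were Dlk1, at 36.0 against 3845 CPM (107-fold, 99.4 to 115), Igfbp2 by 385-fold (164 to 1191), Agtr2 by 192-fold (122 to 320) and the fibrillin gene Fbn2 by 53.5-fold (48.7 to 58.8). The mesenchymal cells lay mainly in clusters 1 and 14 at P0 and in 28 and 31 at P60.

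In macrophages the genes with the largest ratios of P60 to P0 included the MHC class II genes H2-Ab1 and H2-Aa and the invariant chain gene Cd74. H2-Ab1 stood at 7118 against 12.7 CPM (ratio 560, 366 to 904) and H2-Aa at 8457 against 17.0 CPM (ratio 499, 345 to 751). Cd74 stood at 20342 against 211 CPM (ratio 96.3, 86.7 to 107). MHC class II genes were not tested as a group. Ciita, the regulator of these genes, stood at 136 CPM against 0 UMIs, at least 74.7-fold higher, and the lectin gene Mgl2 had a ratio of 305 (166 to 637). Lower at P60 were Crybb1 (517-fold, 175 to 2523, 3 UMIs at P60), Tmem119 (64.2-fold, 40.1 to 109), both known from microglia, and Apoc1 (48.7-fold, 36.1 to 67.0). Most macrophages lay in cluster 9 at P0 and in cluster 13 at P60. The MHC class II genes are markers of the antigen-presenting class, which was named separately. Cluster 13 nevertheless scored second for that class (1.58, against 2.54 for macrophages), whereas cluster 9 scored second for B cells (0.18). The ratios thus compare clusters that differ in these markers.

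Endothelial cells, of which P0 had 30, held less of the imprinted genes H19 (2.05 against 2531 CPM, 1232-fold, 647 to 2700), Mest (90.2-fold, 66.8 to 124) and Peg3 (31.8-fold, 22.9 to 44.8) at P60. The flavin monooxygenase gene Fmo2 (392 CPM, ratio 201, 36.1 to 7951, 1 UMI at P0) and Lrg1 (877 CPM, ratio 75.0, 34.4 to 204) were higher, and the transporter gene Slco1a4 stood at 109 CPM against 0 UMIs, at least 18.7-fold higher. With the strict filter, no doublet removal, list genes kept, each library clustered alone or count splitting, which gave 34 to 303 endothelial cells at P0, H19 was lower by 594- to 2787-fold, Mest by 98.99- to 187-fold and Peg3 by 9.43- to 17.3-fold, and the ratios of Fmo2 and Lrg1 were 198 to 275 and 71.7 to 223.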
